A study of Mus musculus with 12 samples.

How the data were processed

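Polyadenylated RNA was extracted from hippocampus with Trizol and spin columns and made into libraries with an Illumina TruSeq kit, per the labels' protocols. The values used here are raw read counts per gene symbol as deposited by the authors, in 1 table of 12 libraries and 24411 entries. The submitters' processing notes name STAR, DESeq2 and the genome build mm10, with no versions or roles. The gene annotation, any filter and the strand setting of the counting are not given in the sources used here, so reads of overlapping genes on opposite strands may have been counted for either. Genes with near-identical copies, such as class I genes and interferon-induced families, are uncertain for the same reason. The human tau transgene was not analysed here, nor whether its reads were counted for the mouse gene Mapt.

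Of the deposited entries, 27 carry dates in place of gene symbols, a known effect of spreadsheet programs, and hold 0.285% to 0.363% of each library's counts. These were left out of normalisation and tests, which left 24384 genes. The library totals printed below include them. Mitochondrially encoded genes were not analysed here, and the blood cell list, of which 1 gene was tested (Alas2, 1.53 to 4.19 CPM), was not tested as a list. Positions came from GENCODE M21 on mm10, which matched 15962 of the 16618 tested genes by symbol.

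Libraries were grouped by the condition in the labels. Counts were normalised by TMM, and genes with low counts were removed with filterByExpr by group (minimum count 10, minimum total 15). All 12 libraries were fitted in edgeR 4.0.16 (R 4.3.3) with group and labelled sex as terms. By sex-linked counts the labels of littermates F3 and M3 were crossed, so this term was wrong for both in the main fits and list tests. List results are given with labelled sex only. Each of the 3 group contrasts and the sex term were tested with the quasi-likelihood test, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Differences of a change between sexes were tested as contrasts of the 6 group and sex cells in the same kind of fit. The common dispersion was 0.0849, with a prior of 3.86 degrees of freedom and 8 residual degrees of freedom. Values printed as CPM use the TMM-scaled totals, and 3 counts correspond to 0.0517 to 0.11 CPM depending on the library. Counting error is small at these depths except for genes near 1 CPM. Intervals of log2 fold changes cover the spread between libraries. Those of medians over genes were drawn by resampling genes and do not cover it.

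The 38 gene lists were fixed before the data were examined, together with the design and the rule for naming genes. They cover the transgene and its insertion sites, microglia, complement, interferon, antigen presentation, astrocytes, myelin, heat shock, lysosome and other pathways, and markers of hippocampal cell types and neighbouring tissue. Those with at least 5 tested genes (36) were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, with adjustment over the lists, and again with an estimated correlation and with fry. Some lists share genes, such as Ctss in the class II and lysosome lists. A list score is the mean log2 deviation of its genes from their average over the 12 libraries.

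The genes named are, for each group contrast, up to 6 called genes in each direction with the largest fold, a mean of at least 1 CPM and groups that do not overlap. In addition, up to 4 members with the smallest p of each list described and every transgene and insertion-site gene were eligible. Where fewer than 5 genes were called, the 10 with the smallest p are named, and for sex terms 5. Some genes this rule takes are not reported here, and none was put in their place. Other members that passed adjusted over a list alone were named after their values were seen. Clock genes and neighbouring chromosome 12 genes in the closing section were chosen after the data were seen.

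The procedure was tested on counts simulated from the means and dispersions of the libraries, independently for each gene. In these counts 200 of 16618 genes were changed between rTg4510+3TC and rTg4510. The procedure recovered 76% of genes changed by 1 log2 unit and 89% of those changed by 2. It made 5 false calls and 0 calls in the unchanged comparison of rTg4510 with littermates. A list shifted by 0.5 had an adjusted p of 4.08e-10 in camera and 0.00976 with an estimated correlation. No 2 libraries of a group were alike within sampling noise, with a chi-square per gene of 16.9 or more between replicates.

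Alternatives tried were DESeq2 size factors, no filter, a stricter filter (1 CPM in 4 libraries) and the DESeq2 1.42.0 Wald test. Limma-voom was run with and without sample quality weights. Further alternatives were no sex term, the replicate code as a block and the 8 libraries of a comparison alone. The last were a fold threshold of 1 log2 unit and leaving out each library. Added after the data were seen were the exchanged sex of 2 littermate libraries, fits without 3 libraries with neighbouring-tissue markers (rTg4510 F3, rTg4510+3TC F2 and littermate M2), fits without the 3 libraries highest in Ttr (rTg4510 M1, littermate F1 and littermate F3), 2 surrogate variables (sva 3.50.0) and the share of opposite signs, with relabelled libraries, at an unadjusted p under 0.01.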

Results

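Gene expression was measured by sequencing polyadenylated RNA from mouse hippocampus in 12 libraries, which fall into 3 groups of 4. The rTg4510 mouse expresses a mutant human tau transgene in forebrain neurons and is used as a model of tauopathy. The other groups were littermate controls and rTg4510 mice treated with 3TC (lamivudine), a nucleoside inhibitor of reverse transcriptase. By the labels, each group holds 2 females and 2 males. Age, dose and length of treatment are not given in the sources used here. The series title asks how 3TC alters the hippocampal expression of inflammation genes in this model. Library totals were 27286787 to 58173678 counts in littermates, 29732904 to 36112922 in rTg4510 and 27351630 to 35357415 in rTg4510+3TC (n = 4 each). Nothing in the labels says that each library came from a separate animal, so p-values measure the spread between these libraries.

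Sex-linked genes matched the labels in 10 of the 12 libraries. The library labelled littermate F3 had 1525 counts of the Y-linked gene Ddx3y and 1 count of Xist, the RNA that silences the second X chromosome of females. The library labelled littermate M3 had 23156 counts of Xist and 0 of Ddx3y, which allows a level of up to 3 counts (0.0754 CPM; counting error only). The sex labels of these 2 littermate libraries were therefore crossed relative to their counts. Group membership was unaffected: Prnp, the gene that separated the transgenic groups from littermates most clearly, lay between 684.6 and 785.3 CPM in the 4 littermate libraries and between 1537 and 3016 CPM in the 8 transgenic ones.

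Some libraries carried markers of neighbouring tissue. Ttr, the main transcript of the choroid plexus, reached 3907 CPM in rTg4510 M1, 3404 in littermate F1 and 1871 in littermate F3, against 16.3 to 129 CPM in the other 9 libraries. The thalamic neuron list stood at a score of 2.27 in rTg4510+3TC F2 (mean log2 deviation of its 10 genes from their average over the libraries). In rTg4510 F3 the striatal neuron score was 1.32, the dentate granule neuron score was -1.38 and the myelin score was -1.03. In littermate M2 the myelin score was 0.75, the neocortical neuron score 0.527 and the CA1 pyramidal neuron score -0.58. Its thalamic and striatal scores were -0.073 and -0.069. Littermate F1 had a thalamic score of 0.93 and a striatal score of 0.505. It was nevertheless kept in the fits without neighbouring-tissue libraries, which leave out rTg4510 F3, rTg4510+3TC F2 and littermate M2. The libraries high in Ttr were kept in those fits too. The share of pre-ribosomal RNA (Rn45s) was 0.324% to 1.75% of counts.

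**Figure D1:**
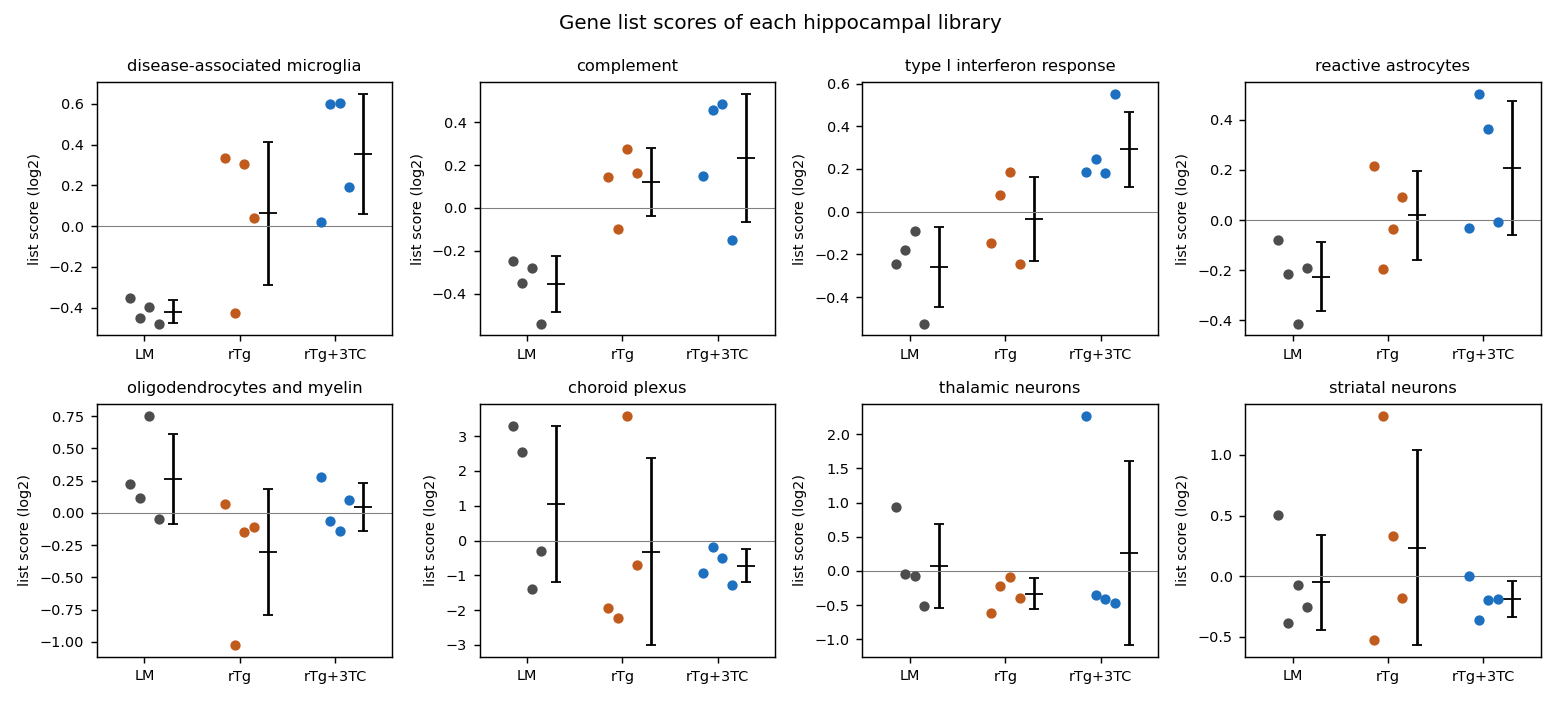
List scores of each library (mean log2 deviation of a list's genes from their average over the 12 libraries, vertical axis) for 8 gene lists, by group (LM, littermate control; rTg, rTg4510; rTg+3TC, rTg4510+3TC). Points are libraries and bars are mean ± SD (n = 4); single libraries stand apart in the thalamic list (2.27) and the striatal list (1.32).

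The comparison of rTg4510 with littermates asks how the hippocampus of this transgenic line differs. It cannot set the tau transgene apart from other features of the line, such as its insertion sites. Of 16618 tested genes, 7 differed, 4 higher and 3 lower in rTg4510. Prnp (chr2, 131909928 to 131938429, mm10), which encodes the prion protein, averaged 2420 ± 200 CPM in rTg4510 and 747 ± 45.2 CPM in littermates (SD, n = 4 each), a log2 fold change of 1.70 ± 0.17 (SE). As background, the tau transgene of this line sits in a vector that carries mouse Prnp sequence. Slc35f1 (chr10, 52690533 to 53111622, mm10), a member of a solute carrier family, rose by 1.12 ± 0.12 on the log2 scale, from 45.4 ± 2.23 to 98.8 ± 17.2 CPM. Car4 (chr11, 84957786 to 84966044), a membrane-bound carbonic anhydrase, rose by 1.25 ± 0.17, from 46.1 ± 6.02 to 110 ± 18.8 CPM. Pmaip1 (chr18, 66458533 to 66465565), which encodes the p53-responsive proapoptotic protein Noxa, rose by 1.35 ± 0.19, from 2.20 ± 0.73 to 5.404 ± 0.651 CPM. Adjusted p was 0.00485 for Prnp and Slc35f1 and 0.0285 for Car4 and Pmaip1 (edgeR quasi-likelihood test, Benjamini-Hochberg). With the sex of littermates F3 and M3 exchanged, a choice made after seeing the data, 5 of the 7 genes passed, and Car4 (1.24, adjusted p = 0.087) and Pmaip1 (1.27, adjusted p = 0.547) did not. The unadjusted p was under 0.05 for 812 genes, where 831 would be expected by chance, and 3.89% of genes had groups that did not overlap, where 2.86% would be expected.

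The 3 genes that fell in rTg4510 are neighbours on chromosome 12. Wdr60 (chr12, 116206262 to 116263022, mm10), a ciliary dynein subunit, had a log2 fold change of -0.86 ± 0.11 (SE), from 27.2 ± 1.33 to 14.96 ± 0.514 CPM (SD, n = 4 each). Esyt2 (chr12, 116281196 to 116391050), an extended synaptotagmin that tethers the endoplasmic reticulum to the plasma membrane, had -0.95 ± 0.12, from 54.9 ± 5.59 to 28.4 ± 1.49 CPM. Ptprn2 (chr12, 116485720 to 117276849), a receptor-type phosphatase of secretory vesicles, had -0.61 ± 0.08, from 415 ± 31.3 to 272 ± 22.6 CPM. Between them, Ncapg2, a condensin subunit, had -1.25 ± 0.26 and did not pass (adjusted p = 0.478, edgeR). Vipr2, the gene that precedes Wdr60 and encodes a receptor for vasoactive intestinal peptide, had 1.70 ± 0.35 and did not pass either (adjusted p = 0.478). These genes belong to a list of 9 transgene and insertion-site genes fixed beforehand, of which 2 rose and 5 fell adjusted over the list alone, and 1 rose and 3 fell over all genes tested. Its other members were Fgf14, at -0.44 ± 0.17, Mapt, the mouse tau gene, at 0.13 ± 0.07, and Camk2a, whose promoter drives the transgene's activator, at -0.07 ± 0.19, a sign that turns without the libraries high in Ttr (0.11). None of these 3 passed over all genes. As a set the list was lower (camera, adjusted p = 0.00223; adjusted p = 0.357 with an estimated correlation), with a median of -0.44. Each list past the threshold was tested again without each library in turn, a choice made after seeing the data. This one did not pass without rTg4510 M1 (adjusted p = 0.0513) or rTg4510+3TC F2 (adjusted p = 0.0555).

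**Figure D2:**
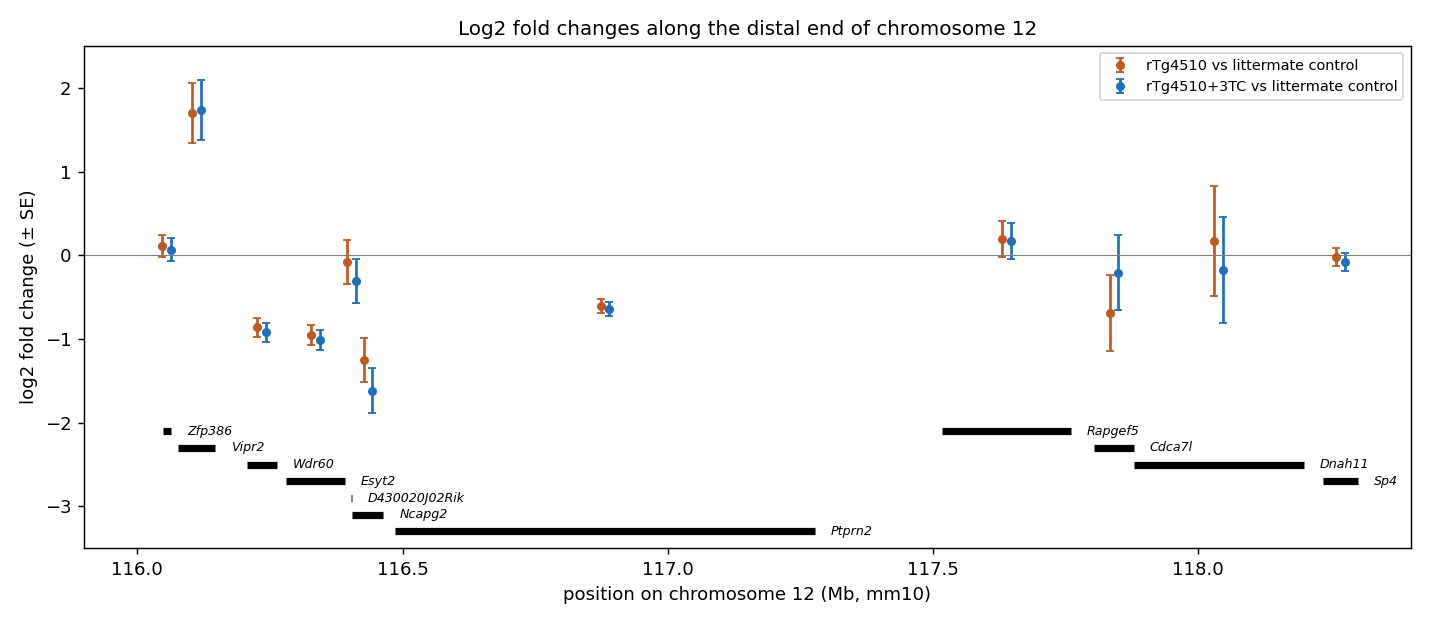
Log2 fold change (± SE, vertical axis) against littermate controls for tested genes at or above 1 CPM along distal chromosome 12 (horizontal axis, Mb, mm10), with gene extents drawn as bars. Wdr60, Esyt2, Ncapg2 and Ptprn2 lie below 0 in both transgenic groups (-0.86, -0.95, -1.25 and -0.61 in rTg4510), and Vipr2 lies above 0 (1.70).

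Microglial and complement genes were higher as lists in rTg4510. In the complement list, 14 of 16 genes had a positive log2 fold change, with a median of 0.51 (camera, adjusted p = 7.3e-11; adjusted p = 0.102 with an estimated correlation). No complement gene passed over all genes tested, and 7 rose adjusted over the list alone, among them C1qa, C1qb, C1qc, C3ar1, C4b and Itgb2. C4b, the classical-pathway component C4, averaged 89.8 ± 47.4 CPM against 27.02 ± 6.43 in littermates (SD, n = 4 each; log2 fold change 1.72 ± 0.44). Itgb2, the integrin beta chain of complement receptor CR3, had 0.81 ± 0.15. In the list of disease-associated microglia genes, 19 of 24 were positive, with a median of 0.24 (adjusted p = 7.64e-06; adjusted p = 0.29 with an estimated correlation). Of these, 3 rose adjusted over the list alone: Clec7a (3.62 ± 0.90), Itgax (3.43 ± 0.72) and Tyrobp (0.74 ± 0.21). Itgax and Clec7a were low throughout, at 0.11 ± 0.08 and 0.12 ± 0.10 CPM in littermates and 1.25 ± 0.33 and 1.49 ± 1.47 CPM in rTg4510. All 12 homeostatic microglia genes were positive, with a median of 0.19 and none past adjustment over the list alone (adjusted p = 0.000194 as a set; adjusted p = 0.523 with an estimated correlation). Lysosomal genes had a median of 0.15, with 21 of 25 positive and none past adjustment over the list alone (adjusted p = 4.92e-06; adjusted p = 0.391 with an estimated correlation). The library rTg4510 F3 stood apart from its group, with a disease-associated score of -0.425 (0.042 to 0.336 in the other 3; -0.478 to -0.352 in littermates) and 22.06 CPM of C4b (98.27 to 132.1 in the other 3). Its complement score was -0.1, against 0.143 to 0.274 in the other 3 and -0.539 to -0.249 in littermates. At the preset correlation these 4 lists passed without each library in turn. The homeostatic median was then 0.07 without rTg4510 F3 and 0.13 without littermate F1, and the lysosomal median 0.09 without rTg4510 M1 and 0.23 without littermate M2.

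Reactive astrocyte genes had a median of 0.31 in rTg4510, with 17 of 23 positive (camera, adjusted p = 0.000558; adjusted p = 0.29 with an estimated correlation). Aspg and S100a10 rose adjusted over the list alone, by 1.10 ± 0.28 and 0.50 ± 0.14. Gfap, the astrocyte intermediate filament, stood at 738 ± 424 CPM against 381 ± 70.3 CPM (0.96 ± 0.43, not past the threshold). In rTg4510 F3 Gfap stood at 213.2 CPM, against 686.2 to 1243 in the other 3, and the reactive astrocyte score was -0.197, against -0.035 to 0.214 in those and -0.413 to -0.081 in littermates. Class I antigen presentation genes had a median of 0.20, with B2m at 0.36 ± 0.12 (adjusted p = 7.14e-05; adjusted p = 0.132 with an estimated correlation). Class II genes had a median of 0.50, and Ctss, a cathepsin of antigen processing, was the gene that rose adjusted over that list alone, by 0.58 ± 0.18 (adjusted p = 0.00176; adjusted p = 0.29 with an estimated correlation). Type I interferon response genes had a median of 0.17, with 21 of 32 positive and none past adjustment over the list alone (adjusted p = 0.0348; adjusted p = 0.527 with an estimated correlation). Heat shock genes had a median of 0.13 (adjusted p = 0.00334; adjusted p = 0.48 with an estimated correlation). Striatal neuron markers, which were highest in the library rTg4510 F3, had 0.39 (adjusted p = 0.0348; adjusted p = 0.69 with an estimated correlation). Without single libraries, the reactive astrocyte median was 0.17 (littermate M2) and the class II median 0.32 (rTg4510 F3) and 0.17 (rTg4510 M3), and both lists passed. Interferon genes did not pass without rTg4510 F3 (0.125, adjusted p = 0.102), rTg4510 M1 (0.00, adjusted p = 0.326) or littermate M3 (0.09, adjusted p = 0.354), nor heat shock genes without rTg4510 M1 (0.08, adjusted p = 0.118). The striatal median turned to -0.04 without rTg4510 F3 (adjusted p = 0.582) and was 0.585 without rTg4510 F2. That list did not pass without rTg4510 M1 (adjusted p = 0.118) or littermate F3, M2 or M3 either (adjusted p = 0.302, 0.0627 and 0.0719).

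The myelin list was lower in rTg4510, with all 14 genes negative and a median of -0.58 (camera, adjusted p = 1.55e-15; adjusted p = 0.29 with an estimated correlation). Cldn11, Mal and Opalin fell adjusted over the list alone, with log2 fold changes of -0.72 ± 0.23, -0.72 ± 0.24 and -0.71 ± 0.21. Mal, a proteolipid of myelin, stood at 183.0 ± 61.9 CPM against 301.9 ± 83.1 CPM (SD, n = 4 each). The lowest myelin score of the 12 libraries was in rTg4510 F3 (-1.03) and the highest in littermate M2 (0.75). Dentate granule neuron markers had a median of -0.30, with Prox1 at -0.89 ± 0.44 (adjusted p = 0.00252; adjusted p = 0.391 with an estimated correlation). Here too rTg4510 F3 was lowest (-1.38). Endothelial and pericyte markers had a median of -0.16 (adjusted p = 0.006; adjusted p = 0.644 with an estimated correlation) and choroid plexus markers -0.31 (adjusted p = 0.0193; adjusted p = 0.776 with an estimated correlation), the last beside the 2 littermate libraries and the rTg4510 library high in Ttr. Without littermate M2, which had the highest endothelial score (0.416), the endothelial median was -0.002 (adjusted p = 0.707). It was -0.139 without rTg4510 M1 (adjusted p = 0.0658) and -0.247 without littermate F3. Myelin passed without each library in turn, at -0.375 without rTg4510 F3 and -0.366 without littermate M2. The dentate list did not pass without littermate M3 (adjusted p = 0.0514), and its median was -0.658 without rTg4510 F2, -0.5 without littermate M2 and -0.167 without littermate F3. The choroid plexus median ran from -3.065 without rTg4510 M1 to 0.889 without rTg4510 F3. That list did not pass without rTg4510 F2, F3 or M3 or littermate F1 or F3 (adjusted p = 0.101 to 0.817). The other 21 lists, among them synapse genes (median -0.004), nucleic acid sensing (0.01) and retroelement control (-0.03), did not pass (smallest adjusted p = 0.0562). Of the 36 lists tested, 15 passed at the preset correlation, 8 of these without each library in turn, and 0 with an estimated correlation, and 3 of the 35 divisions of the 8 libraries gave as many. The count of 7 genes became 2 without rTg4510 F2, M1 or M3 or littermate F1, F3 or M3, 3 without rTg4510+3TC M2 and 4 without rTg4510+3TC M3 or littermate M2. It was 20 with DESeq2, 19 with quality weights and 0 with the replicate code as a block. In fits chosen after seeing the data it was 3 with 2 surrogate variables and 30 without the 3 libraries with neighbouring-tissue markers. Another such fit, without the 3 libraries highest in Ttr, gave 0.

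The comparison of rTg4510+3TC with rTg4510 asks what the drug changes in the model. No gene passed the threshold among 16618 (edgeR), with 571 at an unadjusted p under 0.05 where 831 would be expected by chance, 1 called by DESeq2 and 0 by limma-voom. For genes at or above 1 CPM the median 95% interval reached 0.32 on either side of the log2 fold change. In simulated counts with 200 genes changed, 76% of those changed by 1 log2 unit and 89% of those changed by 2 were recovered. Genes were drawn independently there, without the tissue differences that move many genes together, so recovery in the real comparison may be lower. The 10 genes with the smallest p, none of which passed (adjusted p = 0.999), included Pard3, a cell polarity scaffold, at 35.3 ± 4.78 CPM with 3TC and 23.3 ± 2.45 without (SD, n = 4 each; log2 fold change 0.60 ± 0.13). Plin2, a lipid droplet coat protein, had 0.59 ± 0.16, Polr3gl 0.35 ± 0.09 and Zfp747 0.57 ± 0.15. Rprm, a p53-responsive cell cycle gene, had -0.88 ± 0.24, Ccdc62 -0.92 ± 0.25 and Abcb6 -0.38 ± 0.10. The scarce transcripts Krt83, at 0.65 ± 0.36 CPM with 3TC and 0.02 ± 0.03 without, and Snord95, at 0.01 ± 0.03 and 0.53 ± 0.24 CPM, were also among them. Ptprv had 0 counts in all 4 treated libraries and 6 to 65 in the rTg4510 ones, at least 40.6-fold lower against a floor of 3 counts over the treated group (26.4-fold without rTg4510 F3, which held 65 of the 124 counts), and was the gene that DESeq2 called.

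None of the 7 genes that separated rTg4510 from littermates passed between rTg4510 with and without 3TC (adjusted p = 0.999, edgeR). Prnp averaged 2409 ± 631 CPM with the drug (SD, n = 4; log2 fold change against rTg4510 -0.01 ± 0.16), Slc35f1 106.2 ± 8.03 (0.11 ± 0.11), Car4 115.4 ± 31.8 (0.06 ± 0.17) and Pmaip1 6.129 ± 1.9 (0.13 ± 0.18). Esyt2 averaged 27.2 ± 4.30 CPM (-0.06 ± 0.12), Wdr60 14.3 ± 1.90 (-0.06 ± 0.11) and Ptprn2 265 ± 12.4 (-0.04 ± 0.08). Of the other transgene and insertion-site genes, Vipr2 averaged 4.65 ± 2.02 CPM (0.03 ± 0.34), Mapt had 0.04 ± 0.07, Fgf14 -0.04 ± 0.17, Ncapg2 -0.37 ± 0.26 and Camk2a -0.25 ± 0.19, and none of the 9 passed. The signs of Prnp, Fgf14, Ptprn2, Wdr60 and Vipr2 in this comparison turn under other settings. For Slc35f1, Car4 and Pmaip1, named in this comparison after their values were seen, other settings were not analysed here.

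Among the lists, glial and interferon genes were higher with 3TC than without at the preset correlation. Type I interferon response genes had a median log2 fold change of 0.23, with 25 of 32 positive (camera, adjusted p = 0.00129; adjusted p = 0.686 with an estimated correlation). None passed over all genes or adjusted over the list alone, and Rtp4, a gene of the list, had 1.15 ± 0.51. Disease-associated microglia genes had a median of 0.15, with 20 of 24 positive and Spp1 (osteopontin) at 1.05 ± 0.50 (adjusted p = 0.00278; adjusted p = 0.686 with an estimated correlation). Reactive astrocyte genes had a median of 0.22, with Ggta1 at 0.58 ± 0.21 (adjusted p = 0.0122; adjusted p = 0.686 with an estimated correlation). Astrocyte markers had 0.12, with Sox9 at 0.30 ± 0.11 (adjusted p = 0.00278; adjusted p = 0.686 with an estimated correlation), and heat shock genes had 0.14 (adjusted p = 0.0231; adjusted p = 0.771 with an estimated correlation). All 14 myelin genes were positive, with a median of 0.30 and Ermn at 0.50 ± 0.23 (adjusted p = 1.95e-06; adjusted p = 0.686 with an estimated correlation). Without rTg4510 F3 and rTg4510+3TC F2, left out after seeing the data, the myelin median was 0.02 and the list did not pass (adjusted p = 0.626). The interferon and astrocyte lists passed without each library in turn, at 0.36 without rTg4510 M1 and 0.08 without rTg4510+3TC F2. Without rTg4510 F3 alone, the disease-associated (0.05, adjusted p = 0.208), reactive astrocyte (0.12, adjusted p = 0.173), heat shock (0.07, adjusted p = 0.116) and myelin lists (0.09, adjusted p = 0.0837) did not pass. Without rTg4510+3TC F3 the first 3 did not (0.07, 0.13 and 0.13; adjusted p = 0.156, 0.24 and 0.0777). Reactive astrocyte (0.15, adjusted p = 0.134) and heat shock genes (0.10, adjusted p = 0.383) did not pass without rTg4510+3TC M2, nor heat shock genes without rTg4510 F2 or M3 (adjusted p = 0.069 and 0.145). The disease-associated and myelin medians were 0.24 and 0.52 without rTg4510 F2, and the myelin median 0.18 without rTg4510+3TC F2.

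Markers of neighbouring tissue moved in this comparison as well. Thalamic neuron markers had a median of 0.76, with Tcf7l2 at 49.4 ± 74.6 CPM with 3TC and 10.8 ± 1.09 without (adjusted p = 0.00578 for the list; adjusted p = 0.771 with an estimated correlation). The library rTg4510+3TC F2 held the high value, at 161.3 CPM of Tcf7l2. Striatal markers had a median of -0.54, with Drd1 at -0.70 ± 0.29 (adjusted p = 0.00278; adjusted p = 0.686 with an estimated correlation), beside the high score of rTg4510 F3. Dentate granule markers had a median of -0.24 (adjusted p = 0.0145; adjusted p = 0.686 with an estimated correlation), although their mean score was 0.04 higher with 3TC. The other 27 lists did not pass (smallest adjusted p = 0.084), among them complement (median 0.24), homeostatic microglia (-0.04), nucleic acid sensing (0.00), retroelement control (0.01) and the cytokine and NF-kB list (0.06). Without rTg4510 F3 and rTg4510+3TC F2, the homeostatic microglia median turned to 0.09 (adjusted p = 0.0498; unadjusted p = 0.395 with an estimated correlation) and complement had 0.22 (adjusted p = 0.042; unadjusted p = 0.241 with an estimated correlation). The thalamic (-0.09) and striatal (-0.17) lists then did not pass (adjusted p = 0.764 and 0.399). Without rTg4510+3TC F2 alone, the thalamic median was -0.19 (adjusted p = 0.81) and the dentate median -0.02 (adjusted p = 0.474). Without rTg4510 F2 they were 0.57 (adjusted p = 0.144) and -0.05 (adjusted p = 0.144). The dentate list did not pass without rTg4510 M3 (adjusted p = 0.055) and had -0.435 without rTg4510+3TC F3. The striatal list did not pass without rTg4510 F3 (-0.19, adjusted p = 0.619) or rTg4510+3TC F3 (-0.41, adjusted p = 0.0656). Of the 9 lists past the threshold, 2 passed without each library in turn and 0 with an estimated correlation, and 24 of the 35 divisions of the 8 libraries gave as many.

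The comparison of rTg4510+3TC with littermates asks how far treated animals lie from controls. Here 10 of 16618 genes differed, 5 higher and 5 lower. The 7 genes of the rTg4510 comparison were all among them and moved the same way: Prnp 1.68 ± 0.17, Pmaip1 1.48 ± 0.19, Car4 1.31 ± 0.17, Slc35f1 1.23 ± 0.12, Esyt2 -1.02 ± 0.12, Wdr60 -0.92 ± 0.11 and Ptprn2 -0.65 ± 0.08 (log2 fold change ± SE). The further 3 were Itgb2, Dmpk and Rilpl1. Itgb2 (chr10, 77530252 to 77565708) stood at 11.8 ± 0.74 CPM against 5.06 ± 0.80 in littermates (SD, n = 4 each; 1.23 ± 0.15, adjusted p = 0.0118, edgeR). Dmpk (chr7, 19083849 to 19093821), the kinase whose repeat expansion causes myotonic dystrophy, stood at 18.4 ± 1.81 against 29.6 ± 1.66 (-0.68 ± 0.10, adjusted p = 0.0443). Rilpl1 (chr5, 124493080 to 124531391), a regulator of ciliary protein transport, stood at 48.8 ± 5.45 against 70.1 ± 2.12 (-0.53 ± 0.08, adjusted p = 0.0359). In untreated rTg4510 these 3 genes averaged 8.86 ± 0.99, 23.2 ± 2.31 and 57.2 ± 2.92 CPM, between the other groups, and none differed between rTg4510 with and without 3TC by the test. With the sex of littermates F3 and M3 exchanged, 7 of the 10 genes passed, and Dmpk (adjusted p = 0.0563), Rilpl1 (adjusted p = 0.0563) and Pmaip1 (adjusted p = 0.176) did not. Among the transgene and insertion-site genes, 3 rose and 5 fell adjusted over the list alone, Ncapg2 (-1.62 ± 0.27), Vipr2 (1.73 ± 0.36), Fgf14 (-0.48 ± 0.17) and Mapt (0.17 ± 0.07) included. Camk2a had -0.33 ± 0.19. The list as a set was lower (adjusted p = 0.000164; adjusted p = 0.15 with an estimated correlation) and did not pass without rTg4510+3TC F2 (adjusted p = 0.233). The unadjusted p was under 0.05 for 1353 genes, where 831 would be expected by chance, and 5.86% of genes had groups that did not overlap, where 2.86% would be expected.

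**Figure D3:**
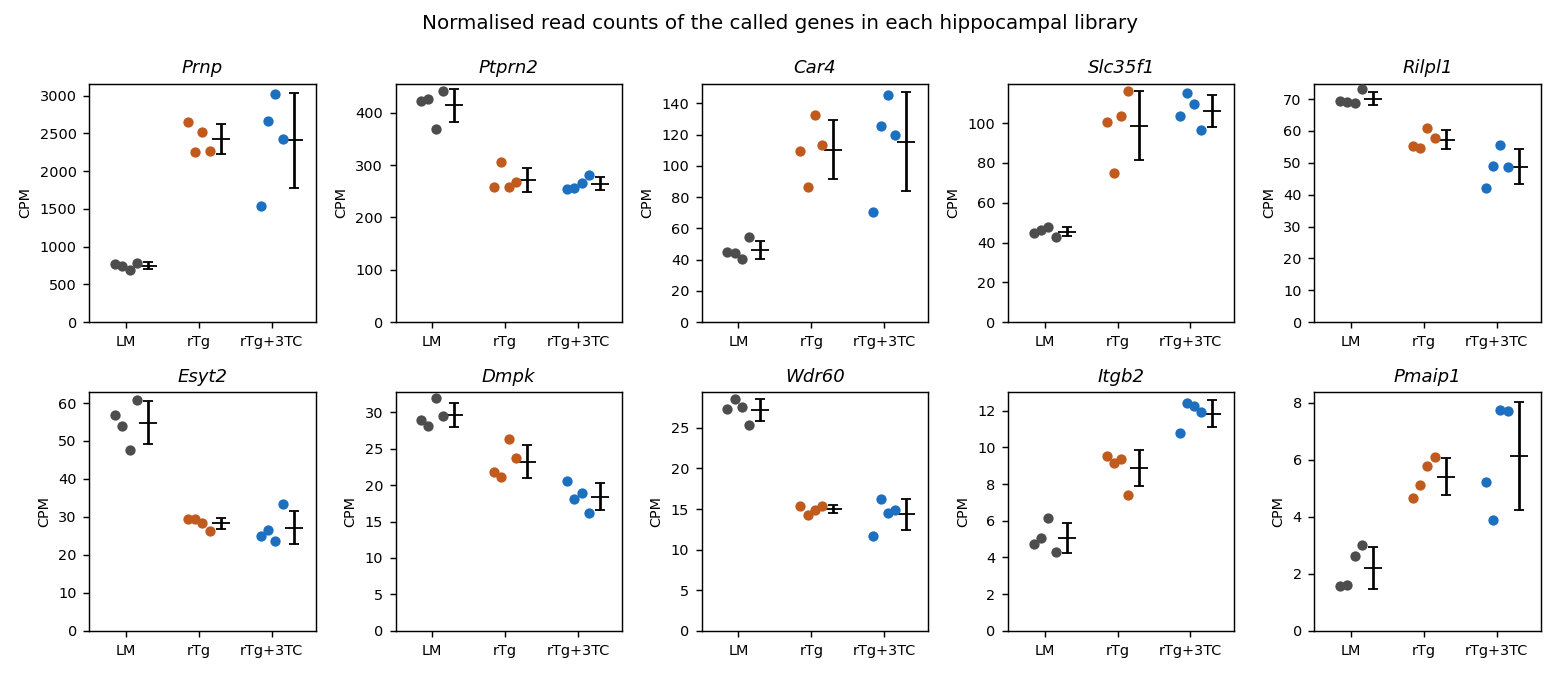
CPM of the 10 genes called between rTg4510+3TC and littermate controls in each library (vertical axes start at 0), by group (LM, littermate control; rTg, rTg4510; rTg+3TC, rTg4510+3TC). Points are libraries and bars are mean ± SD (n = 4); Prnp averages 747, 2420 and 2409 CPM and Itgb2 5.06, 8.86 and 11.8 CPM in the 3 groups.

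The complement list was the one with the lowest p in treated animals, with a median of 0.52 and 11 of 16 positive (camera, adjusted p = 1.49e-11; adjusted p = 0.0756 with an estimated correlation). Itgb2 passed over all genes, and 7 rose adjusted over the list alone: C1qa (0.85 ± 0.17), C1qb (0.80 ± 0.16), C1qc, C3, C3ar1, C4b (2.06 ± 0.45) and Itgb2. Disease-associated microglia genes had a median of 0.31, with 20 of 24 positive, and Cd52, Clec7a, Ctsz, Itgax, Trem2 and Tyrobp rose adjusted over the list alone (adjusted p = 4.34e-11; adjusted p = 0.0756 with an estimated correlation). Itgax had 4.43 ± 0.73 and Clec7a 4.48 ± 0.92, from 0.11 and 0.12 CPM in littermates. Lysosomal genes had a median of 0.23, with 7 of 25 risen adjusted over the list alone, Ctss (0.77 ± 0.18) and Ctsz (0.52 ± 0.15) included (adjusted p = 5.13e-09; adjusted p = 0.175 with an estimated correlation). Reactive astrocyte genes had a median of 0.47, with 21 of 23 positive, and Aqp4, Aspg, Gbp2, Gfap, Ggta1 and S100a10 rose adjusted over the list alone (adjusted p = 4.75e-08; adjusted p = 0.0756 with an estimated correlation). Type I interferon response genes had a median of 0.435, with 30 of 32 positive, and the chemokine gene Cxcl10 rose adjusted over the list alone, from 0.02 ± 0.02 to 0.74 ± 0.45 CPM (adjusted p = 5.85e-07; adjusted p = 0.0763 with an estimated correlation). The gene Irf9 ran the other way, at -0.56 ± 0.19. These 5 lists passed at the preset correlation without each library in turn.

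Heat shock genes had a median of 0.205 in treated animals, and Hsp90aa1, Hspa4l, Hspa8 and Hsph1 rose adjusted over the list alone (camera, adjusted p = 1.72e-06; adjusted p = 0.15 with an estimated correlation). Class I genes (median 0.27, adjusted p = 0.000136; adjusted p = 0.0756 with an estimated correlation), class II genes (0.72, adjusted p = 0.00262; adjusted p = 0.209 with an estimated correlation) and markers of monocytes, neutrophils and border macrophages (0.58, Mrc1 at 0.82 ± 0.30, adjusted p = 0.00338; adjusted p = 0.0756 with an estimated correlation) were higher. So were homeostatic microglia (0.12, adjusted p = 0.0335; adjusted p = 0.714 with an estimated correlation), astrocytes (0.07, adjusted p = 0.0497; adjusted p = 0.6 with an estimated correlation) and cholesterol synthesis genes (0.07, adjusted p = 0.0241; adjusted p = 0.708 with an estimated correlation). Heat shock, class I and macrophage lists passed without each library in turn, with class I at 0.436 without littermate M2 and macrophage markers at a median of 1 without littermate F1. Class II genes did not pass without rTg4510+3TC F3 (0.49, adjusted p = 0.0603). Homeostatic microglia did not pass without rTg4510+3TC F3, M2 or M3 or littermate F1, F3 or M3 (0.025 to 0.109, adjusted p = 0.0636 to 0.328), and had 0.195 without rTg4510+3TC F2 and 0.263 without littermate M2. Astrocytes passed without rTg4510+3TC F3 or littermate M2 (0.178) and not without any of the other 10 libraries (0.006 to 0.091, adjusted p = 0.0506 to 0.336). Cholesterol synthesis genes did not pass without littermate F3 (0.01, adjusted p = 0.575) or rTg4510+3TC F2 or M3 (adjusted p = 0.212 and 0.0667), and had 0.10 without littermate M2.

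Dentate granule neuron markers were lower in treated animals, with all 12 negative, a median of -0.54 and C1ql3 fallen adjusted over the list alone, at -0.68 ± 0.19 (camera, adjusted p = 5.61e-07; adjusted p = 0.0763 with an estimated correlation). The lowest dentate score of the treated group was -0.83, in rTg4510+3TC F2, the library high in thalamic markers, against -0.21 to 0.18 in the others, and the median was -0.36 without it (adjusted p = 0.000113). Immediate early genes had a median of -0.40, with Arc at -1.27 ± 0.45 (adjusted p = 0.00426; adjusted p = 0.622 with an estimated correlation). The library rTg4510+3TC F2 was lowest, at a score of -1.05. Littermates were divided, at 0.714 in M2 and 0.446 in F3 (Arc 430.1 and 255.2 CPM) and -0.26 in F1 and -0.081 in M3 (Arc 83.75 and 122.9 CPM). By Xist and Ddx3y counts, M2 and F3 were male and F1 and M3 female, which the labelled sex term does not follow. With 3TC, Arc was 41.24 and 73.64 CPM in females and 132.5 and 136.7 in males. In rTg4510 it did not divide by sex (73.42 and 130.4 in females, 121.4 and 76.14 in males). The list did not pass without rTg4510+3TC F2 (-0.204, adjusted p = 0.523), littermate F3 (-0.308, adjusted p = 0.164) or littermate M2 (-0.196, adjusted p = 0.0813). Myelin (-0.23, adjusted p = 0.0112; adjusted p = 0.714 with an estimated correlation), endothelial (-0.15, adjusted p = 0.0409; adjusted p = 0.714 with an estimated correlation) and choroid plexus markers (-2.77, adjusted p = 2.67e-05; adjusted p = 0.6 with an estimated correlation) were lower, the last beside the 2 littermate libraries high in Ttr. Littermate M2 had the highest myelin (0.754) and endothelial (0.416) scores, and without it their medians were -0.024 (adjusted p = 0.585) and -0.058 (adjusted p = 0.905). Myelin did not pass without rTg4510+3TC M2 (-0.156, adjusted p = 0.194) and had -0.402 without littermate M3. The endothelial list did not pass without littermate F1 (adjusted p = 0.139) or rTg4510+3TC F3, M2 or M3 (adjusted p = 0.0603, 0.0506 and 0.203), and had -0.231 without littermate F3. Of the 18 lists, 10 passed without each library in turn. The other 18 lists did not pass (smallest adjusted p = 0.104), and fry, which does not compare a list with other genes, called 6 lists. The count of 10 genes became 2 without rTg4510+3TC M2 or littermate F1 or F3, 3 without rTg4510+3TC M3, 4 without rTg4510+3TC F3 and 5 without littermate M3. It was 103 with DESeq2, 63 with quality weights, 0 with the replicate code as a block and 1 with the 8 libraries fitted alone. In fits chosen after seeing the data it was 5 with 2 surrogate variables and 63 without the 3 libraries with neighbouring-tissue markers. Another such fit, without the 3 libraries highest in Ttr, gave 0.

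All 7 genes called in rTg4510 were among the 10 called with 3TC, and both comparisons use the same littermate libraries. Simulated groups without effects called 0.08 genes on average, and comparisons with the littermates divided 2 and 2 called 0 and 0.3, too few to give an overlap to compare with. Of the 7 genes called in rTg4510, 1 had the opposite sign between rTg4510 with and without 3TC (14.3%, exact 95% interval 0.4% to 57.9%), against 78.8% in simulated counts without a drug effect. Dividing the rTg4510 libraries 2 and 2 gave 0%, from the 3 of 6 divisions with any call, and the share was 0% without rTg4510 F2 and 85.7% without rTg4510 F3.

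Sex as labelled gave no gene past the threshold (edgeR), with 471 at an unadjusted p under 0.05, 9 called by DESeq2 and 0 by limma-voom. The smallest p values belonged to Vwf (-0.70 ± 0.14, male against female), Fras1 (-0.64 ± 0.14), Clk1 (0.32 ± 0.07), Alox12 (-1.68 ± 0.36) and Col1a1 (-0.88 ± 0.20), none of which passed (adjusted p = 0.9999). With the sex of the littermate libraries labelled F3 and M3 exchanged, a choice made after seeing the data, 7 genes passed: Xist, Eif2s3x and Ddx3x were higher in females and Ddx3y, Uty, Kdm5d and Eif2s3y in males. No gene had a change in rTg4510 that differed by labelled sex in edgeR, with 1089 at an unadjusted p under 0.05. DESeq2 called 56 and limma-voom 0, and edgeR called 29 without rTg4510 M3. By the Xist and Ddx3y counts, each labelled sex of littermates held both a male and a female library, so this contrast does not test sex. The smallest p values were of the choroid plexus genes Kcne2, Folr1, Rbm47, Ttr and Slc4a5. These were high in the libraries high in Ttr, littermates F1 and F3 and rTg4510 M1. For the difference of the 3TC change by sex, 0 genes passed with edgeR (593 at an unadjusted p under 0.05), DESeq2 or limma-voom, 2 passed without rTg4510 M3 and 4 without rTg4510+3TC F3, with Rassf7, Ptpn18, Otx2, Cacng5 and Zic1 at the smallest p.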

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

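The tests of neuron loss, of myelin and of microglial share, and that of the disease-associated list without 2 libraries, were chosen after the result was seen, and the spread rule for the interferon list was added after its value was seen. The chromosome 12 segment was first cut by the order of gene starts, which left out Gm10421, a gene inside Ptprn2, and was set by position after the values were seen. The use of its genes that were not called, and the tests of lists without single libraries, were chosen after the values were seen as well. A sample far from the other 3 of its group was found 12 times in 147 groups, where chance gives about 1 in 20. The share of Rn45s was 1.747% in rTg4510 M3, against 0.324% to 0.561% in the others. Ttr stood at 3907 CPM in rTg4510 M1, against 16.33 to 85.69. The library rTg4510+3TC F2 stood apart in 4 list scores: thalamic neurons 2.272, homeostatic microglia -0.389, CA1 pyramidal neurons -0.328 and retroelement control -0.064. The homeostatic microglia score was 0.201 in littermate M2 and the cholesterol synthesis score -0.216 in littermate F3. The synapse score was -0.072 in rTg4510 M1 and the nuclear oxidative phosphorylation score -0.007 in rTg4510 M3. Itgb2 stood at 7.396 CPM in rTg4510 M3, against 9.176 to 9.53, and Rilpl1 at 73.3 CPM in littermate M3, against 68.78 to 69.27.

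Esyt2, Wdr60 and Ptprn2 were lower in both transgenic groups than in littermates. Lower sequencing depth is argued against, since all 3 stayed past the threshold when every library was thinned to the smallest total. A broad loss of neurons as the source of these lower counts is argued against by the synapse list. Its median, on the same scale, was -0.004 in rTg4510 and -0.079 in rTg4510+3TC. Counts are scaled to the bulk of genes, so the list does not measure how many neurons were present. Lists of CA1, CA3 and inhibitory neurons did not pass in either group. Dentate granule markers were lower in both (medians -0.296 and -0.537), so a loss of those neurons stays open. A disrupted or deleted segment at a transgene insertion site stays open. The 7 tested genes from Vipr2 to Ptprn2 had a median of -0.608 in rTg4510 and -0.646 in rTg4510+3TC. That median and the median of the flanking genes met what was predicted beforehand for such a segment. The segment median, however, includes the 3 genes that define the pattern, so it cannot decide. The 18 flanking genes had a median of -0.021 in rTg4510 (95% interval over genes -0.087 to 0.128). The 4 tested genes from Vipr2 to Ptprn2 other than Esyt2, Wdr60 and Ptprn2 went both ways (median 0.382). They were Ncapg2 (-1.25 ± 0.26, SE), D430020J02Rik (-0.08 ± 0.27), the scarce Gm10421 (0.85 ± 1.12) and Vipr2 (1.70 ± 0.35), and the sequence of the segment was not analysed here.

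All 14 myelin genes had a negative log2 fold change in rTg4510 against littermates, of which 3 fell adjusted over the list alone (camera, adjusted p = 1.55e-15; adjusted p = 0.29 with an estimated correlation). The list had its lowest score in rTg4510 F3 (-1.027) and its highest in littermate M2 (0.754). Different tissue in these 2 libraries stays open: without them the median was -0.117, with 11 of 14 genes negative (adjusted p = 0.0168; adjusted p = 0.662 with an estimated correlation), but they hold the extremes of this same score, so that leaving them out had to bring the groups closer. An effect of the transgene on myelin genes stays open too, since the list scores of the 2 groups overlapped (two-sided exact permutation p = 0.0571, n = 4 each).

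The interferon and disease-associated microglia lists were higher in rTg4510+3TC than in rTg4510 (camera, adjusted p = 0.00129 and 0.00278; adjusted p = 0.686 with an estimated correlation for both). Neighbouring tissue in rTg4510 F3 and rTg4510+3TC F2 is argued against for the interferon list, whose median was 0.237 without them and 0.226 with them. The 95% interval without them, 0.121 to 0.417, was drawn over genes and does not cover the spread between libraries. With an estimated correlation the list then had an unadjusted p of 0.0504 (camera). For the disease-associated list neighbouring tissue stays open, at 0.104 without those libraries (0.042 to 0.279, over genes) and 0.15 with them. This list did not pass without rTg4510 F3 alone (adjusted p = 0.208) or rTg4510+3TC F3 alone (adjusted p = 0.156). A larger share of microglia stays open too: the disease-associated score moved above the homeostatic score by 0.363 (two-sided exact permutation p = 0.171, n = 4 each), and the homeostatic median turned from -0.035 to 0.093 without those 2 libraries. No biological explanation is set apart by these values, since 24 of the 35 divisions of these 8 libraries gave 9 lists or more.

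Other divisions of the libraries were counted for each comparison. For rTg4510 against littermates, 1 of 35 divisions, the real one, gave 7 genes and the highest other gave 1. That is the smallest share 35 divisions can give, so chance is argued against for the count of genes but not excluded. For its 15 lists chance is not argued against, since 3 of 35 gave as many and the highest other gave 18. For rTg4510+3TC against littermates, 1 of 35 gave 10 genes and the highest other gave 0. The same limit holds there, and the littermate libraries are the same. For its 18 lists chance is not argued against, at 3 of 35 with a highest other of 19. For rTg4510+3TC against rTg4510, the real count was 0 genes, which any division reaches, so that 35 of 35 says nothing on chance, and the highest other gave 2. For its 9 lists chance cannot be excluded, since 24 of 35 gave as many and the highest other gave 15. For sex as labelled the real count was 0 as well, so that 100 of 100 drawn divisions reached it without telling anything on chance, and the highest other gave 1159. That division set rTg4510 F3, littermate M2 and all 4 rTg4510+3TC libraries against the rest. Group was a term of the fit, so the rTg4510+3TC libraries, all on the same side, did not inform this count. The count points to a difference that rTg4510 F3 and littermate M2 share from the other libraries of their groups.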

How the results depend on the processing

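Settings that exchange sex labels, leave out 3 libraries or add surrogate variables were chosen after seeing the data, and the cause of the differences was not tested. Counts are given for rTg4510 against littermates (7 genes) and rTg4510+3TC against littermates (10). With an absolute log2 fold change of 1 or more they were 4 and 6, with DESeq2 20 and 103, with quality weights 19 and 63, with the replicate block 0 and 0, without the neighbouring-tissue libraries 30 and 63, without the libraries highest in Ttr 0 and 0, and with 2 surrogate variables 3 and 5. All 7 and all 10 were shared with DESeq2 and quality weights, 6 and 10 without the neighbouring-tissue libraries, and 2 and 4 with surrogate variables. Exchanged sex labels gave 5 and 7, all shared. The 8 libraries alone gave 1 for the second. Leaving out single libraries gave 2 to 9 and 2 to 14. For rTg4510+3TC against rTg4510, DESeq2 gave 1 and every other setting 0. Sex gave 9 with DESeq2, 7 with exchanged labels and 0 without any single library. Its difference in rTg4510 gave 22 with no filter, 56 with DESeq2, 2 without the neighbouring-tissue libraries and 0 to 29 without single libraries, and its difference under 3TC gave 0 to 4. Without the libraries highest in Ttr, no female-labelled littermate is left and the sex differences have no value. Replicate codes did not pair libraries across groups: 8 pairs with a code in common had r of -0.246 to 0.05.

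Lists past the threshold (15, 9 and 18) became 0, 0 and 0 with an estimated correlation and 0, 0 and 6 with fry. For rTg4510+3TC against rTg4510 they were 14 with the block and 14 without the libraries highest in Ttr, and for rTg4510+3TC against littermates 11 without the latter. Leaving out single libraries gave 12 to 17, 6 to 13 and 14 to 17. The share of opposite signs was 0 with rTg4510 libraries split and 0 to 85.7 without single libraries.

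Of 5100 alternative values for 208 results of named genes, 44 reversed, 159 lost and 71 gained a call, and none of the 44 passed. In rTg4510 against littermates, quality weights gave H2-DMb1 -0.12, Drd2 -0.126 and Drd1 -0.018, surrogate variables Calml4 0.012 and Kl 0.17, the block Camk2a 0.157 and the fit without libraries highest in Ttr Camk2a 0.109. In rTg4510+3TC against rTg4510, the fit without neighbouring-tissue libraries gave Plekhg1 -0.006, Slc17a6 -0.352, Prnp 0.125, Fgf14 0.132 and Ptprn2 0.037. Quality weights gave Prnp 0.058, Fgf14 0.119, Ptprn2 0.005 and Vipr2 -0.005, the block Fgf14 0.035 and Vipr2 -0.242, limma-voom Vipr2 -0.016, the 8 libraries alone Vipr2 -0.006 and the fit without libraries highest in Ttr Vipr2 -0.211. In rTg4510+3TC against littermates the last gave Ttr 0.167. Without single libraries, the first comparison gave Sostdc1 -2.451 to 0.248, Calml4 -2.202 to 0.314, Kl -2.662 to 0.518, Aqp1 -3.855 to 0.797 and Camk2a -0.143 to 0.002. The second gave Tnnt1 -0.137 to 1.992, Slc17a6 -0.377 to 1.737, Prnp -0.132 to 0.162, Fgf14 -0.169 to 0.138, Ptprn2 -0.081 to 0.022, Wdr60 -0.142 to 0.031 and Vipr2 -0.304 to 0.202.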

Other observations

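The clock genes and the genes called by alternatives were picked after their values were seen, as were the tests on relabelled libraries, while the test of the other clock genes was fixed before its value was seen. Clock genes were shifted in both transgenic groups. Between rTg4510+3TC and littermates, Per1 and Per3, repressors of the circadian clock, had log2 fold changes of -0.70 ± 0.11 and -1.11 ± 0.23 (SE, n = 4 each), and Arntl, which encodes the clock activator BMAL1, had 0.71 ± 0.14. None passed in edgeR (adjusted p = 0.0647, 0.192 and 0.192). All 3 were called by DESeq2, by quality weights and without the neighbouring-tissue libraries, which refit the same data and are not independent. A different time of day of tissue collection may account for these shifts. A clock score of 10 other genes was the mean log2 CPM of Per2, Nr1d1, Nr1d2, Dbp, Tef and Ciart minus that of Clock, Npas2, Nfil3 and Cry1. It differed by -0.817 between rTg4510+3TC and littermates (two-sided exact permutation p = 0.0286, the smallest that 4 against 4 can give). Npas2 ran against this, at -0.237 ± 0.164. The score differed by -0.696 between rTg4510 and littermates (exact p = 0.0286). Between rTg4510+3TC and rTg4510 it differed by -0.121 (exact p = 0.629). All 8 transgenic libraries, at 0.521 to 1.483, lay below the 4 littermates, at 1.664 to 1.846. An effect of the transgene on the clock predicts the same and stays open, and collection times are not given in the sources used here.

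The 3 alternatives with the most calls, DESeq2, quality weights and the fit without neighbouring-tissue libraries, had 9 genes in common for rTg4510 against littermates, 4 higher and 5 lower. Beyond genes named above, these were Blnk, a B-cell linker protein (1.62), Npnt, the matrix protein nephronectin (-1.15), and Sipa1l2 (-0.59), as log2 fold changes in edgeR, where they did not pass (adjusted p = 0.468, 0.266 and 0.409). For rTg4510+3TC against littermates they had 30 in common, 17 higher and 13 lower, among them the leukocyte phosphatase Ptprc (1.27), Mpeg1 (0.98), Plek (0.80), C4b (2.06) and Ncapg2 (-1.62), none of which passed in edgeR. For rTg4510+3TC against rTg4510 they had 0 in common. All 3 alternatives refit the same data. Quality weights were lowest in the libraries left out as neighbouring tissue (rTg4510 F3 0.385, rTg4510+3TC F2 0.404 and littermate M2 0.426). Genes in common are therefore not independent support.

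One hypothesis is that 3TC moves expression further from littermates in genes that differ in rTg4510. Most genes used here need not differ. In rTg4510 against littermates, 812 genes had an unadjusted p under 0.05, where 831 would be expected by chance. At an unadjusted p under 0.01, 55.9% of 161 genes had opposite signs in the 2 contrasts. Simulated counts with no drug effect gave 78.5% (76.7% to 80.1%). Genes were drawn independently there, so this range leaves out tissue differences that move many genes together. With the rTg4510 libraries divided the share was 25.4% (14.8% to 45.3%), where 50% would be expected with neither effect nor sharing. Of the 70 relabellings of the 8 transgenic libraries, 1, the real one, gave a share as low (median 83.6%, highest 96.3%). At cutoffs of 0.05 and 0.001 the shares were 70.3% and 45%, as low in 1 and 3 of 70. This is consistent with a further move, but the share depends on libraries: it was 80.8% without rTg4510 F2, 76.2% without rTg4510 M1, 74.8% without rTg4510 M3, 73.9% without the libraries highest in Ttr and 82.4% with the replicate block.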
